A study of Mus musculus with 29 samples.

How the data were processed

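RNA was measured in 29 libraries of 3 groups: 9 control embryos and 8 hydroxyurea-treated embryos, each 1 whole mouse embryo made by nuclear transfer, and 12 single cumulus cells, the cell type that supplied the donor nuclei. Per the labels' protocols, enucleated oocytes of the BDF1 strain received a cumulus cell nucleus, were activated for 6 h in medium with 10 mM strontium, and were then distributed at random into medium without or with 10 uM hydroxyurea, which was replaced after 24 h. Embryos were taken at the 2-cell stage, 28 h after activation. Libraries were made by Smart-seq2, a full-length cDNA method that does not mark strand and carries no molecular identifiers, so intervals and floors below cover counting error only.

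The authors deposited a table of raw counts per gene (24540 rows in 29 columns) and a table of FPKM values with the same rows. Per the submitters' processing notes, FastQC, STAR 2.7.3a and R 4.0.2 were used with the mm10 build. The counter, the annotation and the strand setting are not given in the sources used here. The counts were whole numbers that summed to different totals per library, and 92 rows were ERCC spike-in RNAs, which left 24448 gene rows. Of these, 37 rows carried Ensembl identifiers in place of symbols, and all 37 were matched to the symbols of mitochondrially encoded genes. The deposited FPKM values were checked against the counts: for all 18588 genes with a count in at least 2 libraries, FPKM equalled the count divided by the library's sum without ERCC rows and by 1 whole-number length per gene (tolerance 0.001), so the FPKM table holds no further normalization. No deposited column was left unmapped to a sample. Gene positions come from GENCODE M21 on GRCm38, the assembly called mm10, matched by symbol; the annotation behind the counts may differ from it.

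ERCC rows were left out of library sizes and tests. For hydroxyurea (HU) against control, embryos were compared with the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3 (TMM factors, filterByExpr, no covariate, only the 17 embryos in the fit), with Benjamini-Hochberg adjustment and a threshold of 0.05. Standard errors of log2 fold changes were taken from the F statistic. Means and SDs of genes are TMM-scaled CPM (counts scaled to a common library size). A total of 29 gene lists, fixed before the data were examined, were scored per embryo as the mean log2(CPM + 1) of the members that passed the filter, and compared with a 2-sided exact permutation test over all 24310 splits of the embryos into 9 and 8, adjusted over the 25 lists with at least 5 such members. Library measures, the spread between embryos (mean Euclidean distance to the own group's mean) and a donor score (mean of donor-high genes minus mean of embryo-high genes, both chosen over all 17 embryos without regard to treatment) were compared by the same exact permutation. The labels name no animal or culture for the cumulus cells, so the 12 cells count as 1 sample: their counts were summed, no test was run, and the sum carries an exact Poisson interval at 95%. List medians of the log2 ratio to the control embryos (1 CPM added) were ranked among 10000 random lists of the same size matched on mean expression. Folds against a group without a count use a floor of 3 counts over the whole group. The labels do not say whether embryos came from separate days or females, so p-values measure the spread between these embryos.

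The genes named were fixed by rule: the 12 genes with the largest fold change per direction among those past the threshold with a mean CPM of at least 10, and, where fewer than 5 passed, the 5 with the smallest p per direction at that mean CPM; the 2 passing members per direction of each list or, where none passed, its 2 most abundant members; and Zscan4d, Zscan4c, Zfp352, Xist, Cdkn1a, Rrm2, Pou5f1, Kdm4d and Chek1. Predicted genes, Rik clones and pseudogenes were left out of the first part. For cumulus cells the rule took the 10 genes with the largest ratio each way among those at 100 CPM or more on the higher side with a count in at least 10 of 12 cells or 8 of 9 control embryos, and the 2 most abundant members of each list. Some genes that the rule names are not reported here.

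Both procedures were tested on simulated data. In a simulation of 8 against 9 embryos over 11476 genes, the edgeR fit recovered 32% of genes changed 2-fold, 66% of those changed 4-fold, 78% at 8-fold and 96% at 16-fold, with 7 false calls among 143. It changed 50 genes at each fold and let genes vary independently. Genes of real embryos vary together, so this recovery and these false calls need not hold for the data. The list test called 2.5% of unchanged simulated lists and 100% of lists shifted by 0.5 on the log2 scale, with members that varied independently. Real members vary together: with the real scores of each list, centred by group and shuffled over the embryos, a shift of 0.5 reached an unadjusted p under 0.05 in 18% of 200 draws for the 2-cell list, 38% for ribosomal protein genes, 51% for mitochondrially encoded genes and 55% for housekeeping genes of genome activation. It did so in 75.5% for mitosis, 84% for imprinted and 88.5% for heat shock genes, and in at least 90% for the other 18 lists. Calls were made after adjustment over 25 lists, for which this power was not computed, so the absence of a call does not exclude a shift of 0.5. This second simulation was chosen after seeing the data. Alternatives covered other size factors, DESeq2 1.42.0, limma-voom from limma 3.58.1, other filters, the FPKM values, covariates, a replicate block, each embryo left out in turn, and camera and fry for the lists. After the data were seen, scaling by ERCC counts, library sizes without the 45S pre-rRNA row Rn45s, a 2-cell score covariate, the omission of the embryo with the fewest genes in each group, the omission of cumulus cells 2 and 11, a comparison of SDs of list scores, and the ERCC and Rn45s library measures were added. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 did the rest.

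Total counts ran from 1912312 to 3711937 in control embryos, from 2573421 to 4008700 in HU embryos and from 1197997 to 5782773 in cumulus cells. The Rn45s row took 15.2% to 32.5% of gene counts in embryos and 49.3% to 86.6% in cumulus cells, which leaves fewer counts for messenger RNA. No pair of embryo libraries agreed within sampling noise (lowest chi-square per degree of freedom 14.7), so none was counted as a duplicate.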

Results

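Gene expression was profiled in single 2-cell embryos produced by nuclear transfer, in which the nucleus of a cumulus cell (a somatic cell that surrounds the oocyte) is placed in an enucleated oocyte and activated. Of these embryos, 9 were cultured without and 8 with 10 uM hydroxyurea (HU), an inhibitor of ribonucleotide reductase that lowers nucleotide pools and slows replication forks. In addition, 12 single cumulus cells represent the donor cell type. Control embryos held 13875 to 15132 detected genes, HU embryos 12887 to 15421 and cumulus cells 4054 to 8629. Spearman correlation between embryos, over genes, ranged from 0.868 to 0.919, and between cumulus cells from 0.241 to 0.777.

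The comparison of HU with control embryos asks whether exposure to HU alters the transcripts of the reconstructed embryo. Etnk1, which encodes ethanolamine kinase, had the smallest p of all 11476 genes tested: 49.6 ± 25.5 CPM in HU embryos (SD, n = 8) against 13.6 ± 4.70 CPM in controls (SD, n = 9). The log2 fold change was 1.86 ± 0.32 (SE), with 7 of 8 HU embryos above the highest control. Its edgeR adjusted p was 0.0949, short of the threshold of 0.05. Tmed7, a p24-family gene of vesicle transport, stood at 17.1 ± 5.98 CPM against 4.94 ± 2.7 CPM (log2 fold change 1.79 ± 0.40, SE). Pdxp, pyridoxal phosphatase, stood at 152 ± 47.2 CPM against 77.8 ± 26.4 CPM (0.97 ± 0.23), with 8 of 8 HU embryos above every control. Gprc5c (1.36 ± 0.34) and the palmitoyltransferase gene Zdhhc8 (1.00 ± 0.25) complete the 5 named genes with higher values in HU. In the other direction, Arl14epl stood at 9.19 ± 4.38 CPM in HU against 21.9 ± 4.39 CPM in controls (log2 fold change -1.25 ± 0.33). The other named genes were Naip1 of the Naip family (-1.27 ± 0.39), Lnx2 (-0.84 ± 0.25), the general transcription factor gene Gtf2b (-0.77 ± 0.23) and the palmitoyltransferase gene Zdhhc3 (-0.65 ± 0.20). For these 5 genes, 0 of 8 HU embryos exceeded the control median. Genes of both directions were chosen by their p in these same embryos, so such counts of embryos are no separate support.

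In the edgeR quasi-likelihood test, 0 genes were higher and 0 lower at an adjusted p under 0.05, and the 9 named genes other than Etnk1 had an adjusted p of 0.83. At an unadjusted p under 0.05 there were 671 genes (5.85%), 437 higher and 234 lower in HU. Single embryos moved these counts both ways. Without HU 5 there were 282 higher and 158 lower, and without control 3 there were 642 higher. There were 424 lower without HU 1 and 353 lower without HU 8. A fit with all 3 groups, whose dispersion also covers the cumulus cells, gave 42 higher and 18 lower of 11924 genes (0.503%). A fit without a filter on low counts gave 1193 higher and 797 lower of 19499 genes (10.2%). DESeq2 called 2 genes higher (Etnk1, adjusted p 0.000199, and Tmed7, 0.0221) and 1 lower (Shq1, 0.0403; named after its values were seen). Limma-voom called 0, with 350 genes higher and 356 lower at an unadjusted p under 0.05. Scaling by ERCC counts, chosen after seeing the data, moved the median log2 fold change of all genes from 0.04 to 0.19. It split the genes at an unadjusted p under 0.05 into 617 higher and 25 lower, still with 0 calls, so the balance of directions depends on the scaling and the tool. Etnk1 lies on chromosome 6 (143167221 to 143232307, plus strand, GRCm38) and is overlapped by the antisense gene 1700126G02Rik. Tmed7 on chromosome 18 (46560235 to 46597535, minus strand) overlaps Ticam2 on the same strand, and Zdhhc3 on chromosome 9 (123066160 to 123113205, minus strand) overlaps Tgm4 on the opposite strand. Counts of overlapping genes cannot be told apart without the counting rules, and those of Naip1 can be shared with its paralogs. Pdxp on chromosome 15 (78913919 to 78919517) is overlapped by the protein-coding gene Gm49510 on the same strand, Gtf2b by the small nuclear RNA gene Gm24457 and Naip1 by the pseudogene Rpl31-ps13, both on the opposite strand. Arl14epl lies on chromosome 18 (46921815 to 46934232).

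**Figure D1:**
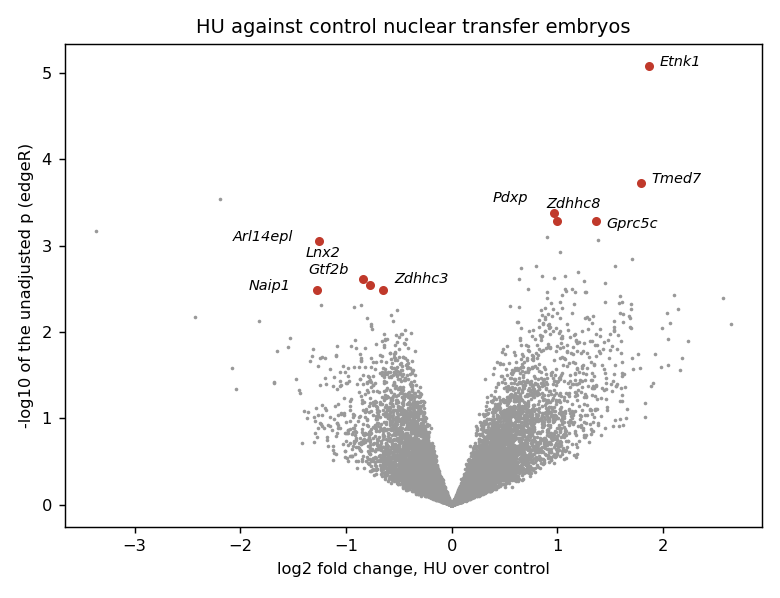
Each point is 1 of the 11476 genes, with the log2 fold change of HU over control embryos on the x axis and -log10 of the unadjusted edgeR p on the y axis; red points are the 10 named genes with the smallest p per direction. Etnk1 stands highest at a log2 fold change of 1.86, and no gene reached an adjusted p under 0.05.

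Genes of the 2-cell stage, such as Sp110 and Zfp352, are switched on when the embryonic genome is first transcribed. Sp110 stood at 680 ± 750 CPM in HU (SD, n = 8) and 310 ± 379 CPM in controls (SD, n = 9; log2 fold change 1.14 ± 0.62, SE). AF067063 stood at 231 ± 259 against 127 ± 167 CPM (0.87 ± 0.64), and the 2-cell gene Zfp352 at 99.5 ± 98.3 against 47.5 ± 42.7 CPM (1.07 ± 0.59). Of the 31 measured members of the 2-cell list, 26 had a fitted fold change above 0 and 0 passed. The list score was 5.11 ± 1.17 in HU and 4.6 ± 0.86 in controls. The difference was 0.51 ± 0.51 (SE; exact permutation p = 0.312, adjusted p = 0.908), with 5 of 8 HU embryos above the control median. It was 0.79 without control 3 and 0.29 without HU 4. Zscan4d and Zscan4c, members of a cluster of near-identical copies whose counts are therefore uncertain, fell below the filter: Zscan4d had counts in 5 of 9 control embryos, at most 107 in control 3, and in 4 of 8 HU embryos, at most 18 in HU 3. Zscan4c had counts in 3 of 9 and 4 of 8 embryos. The list of housekeeping genes of genome activation scored 6.22 ± 0.53 in HU against 6.11 ± 0.38 (difference 0.10, exact permutation p = 0.643), with the nucleolar gene Npm1 at 725 ± 403 against 521 ± 135 CPM and the initiation factor gene Eif1 at 803 ± 309 against 869 ± 166 CPM.

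Maternal oocyte transcripts, which are laid down in the egg and cleared at this stage, were the list with the smallest p. Its score was 7.22 ± 0.34 in HU and 7.44 ± 0.16 in controls, with 2 of 8 HU embryos above the control median. The difference was -0.22 ± 0.13 (SE; exact permutation p = 0.0908, adjusted p = 0.908), and -0.13 without HU 5 and -0.0969 with ERCC scaling. A total of 47 of 59 measured members had a fitted fold change below 0 and 0 passed. Spin1 stood at 6242 ± 2737 CPM in HU against 7446 ± 1436 CPM, and Tcl1, from a multigene family, at 6040 ± 2238 against 7581 ± 1385 CPM. Among pluripotency and preimplantation factors (difference -0.02, above 0 with ERCC scaling, exact permutation p = 0.83), 0 of 25 members passed. Obox5 was at 497 ± 210 CPM in HU and 789 ± 301 CPM in controls (log2 fold change -0.67 ± 0.27). Pou5f1, the Oct4 gene, stood at 204 ± 68.1 against 261 ± 64.8 CPM, and Klf17 at 670 ± 313 against 580 ± 155 CPM.

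**Figure D2:**
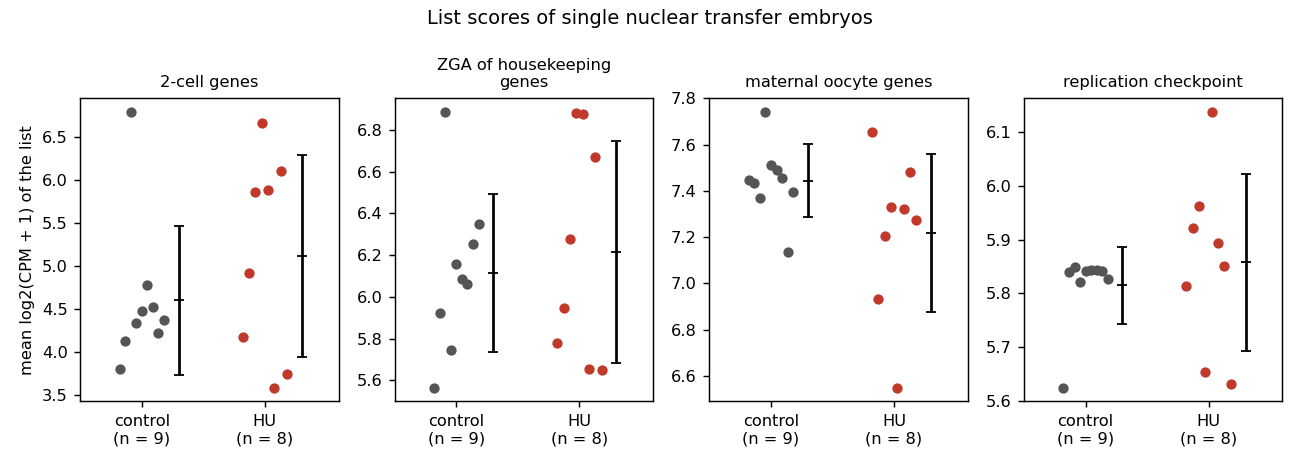
Scores (mean log2(CPM + 1) of the list members) of 9 control embryos in grey and 8 HU embryos in red for 4 gene lists; each point is 1 embryo, and the bar is the mean with its SD. The 2-cell scores of control 3, at 6.79, and of several HU embryos lie above the other controls, and the groups overlap in each panel.

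Genes of the replication stress response were examined because HU acts on nucleotide supply. Per the labels, HU was replaced after 24 h and embryos were taken 28 h after activation. Transcripts may thus have been read after its removal, and replication itself was not measured here. The kinase gene Chek1 stood at 317 ± 82.6 CPM in HU (SD, n = 8) and 329 ± 53.5 CPM in controls (SD, n = 9), a log2 fold change of -0.05 ± 0.16 (SE), and Rrm2, the ribonucleotide reductase subunit, at 200 ± 86.4 against 250 ± 139 CPM (-0.32 ± 0.29). The p53 target Cdkn1a, which encodes p21, stood at 132 ± 57.7 against 105 ± 44.7 CPM (0.33 ± 0.27), and Rrm2b at 244 ± 56.8 against 306 ± 66.3 CPM (-0.32 ± 0.17). None of the 40 checkpoint genes, 50 replication genes, 44 nucleotide synthesis genes, 37 break repair and Fanconi genes or 29 p53 targets passed. Score differences were 0.04 for the checkpoint list (exact permutation p = 0.511) and 0.11 for replication (p = 0.439, exact permutation). They were 0.04 for nucleotide synthesis (p = 0.545, exact permutation; below 0 in FPKM), 0.09 for break repair (p = 0.222, exact permutation) and 0.07 for p53 targets (p = 0.434, exact permutation). The most abundant members were the egg kinase gene Wee2 (1531 ± 395 against 1822 ± 214 CPM), Dbf4 (965 ± 222 against 1134 ± 231 CPM), and the polymerase subunit gene Pold3 (332 ± 83.7 against 397 ± 78.9 CPM). The origin recognition gene Orc6 (354 ± 110 against 372 ± 88.5 CPM), Mthfd2 (352 ± 116 against 399 ± 58.2 CPM), and the dUTPase gene Dut (343 ± 133 against 404 ± 139 CPM) complete the replication and nucleotide lists. The other abundant members were the repair gene Brca2 (341 ± 86.5 against 359 ± 73.2 CPM) and the p53 target Ei24 (175 ± 82.0 against 156 ± 39.1 CPM). Mitosis genes had a difference of 0.22 (exact permutation p = 0.266). Of 41 members, 32 were above 0, with Ccna2 at 693 ± 200 against 597 ± 114 CPM and Ccnb1 at 656 ± 338 against 552 ± 173 CPM.

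Chromatin genes bear on reprogramming of the donor nucleus. The H3K9 demethylase gene Kdm4d was at 5.70 ± 4.21 CPM in HU and 2.84 ± 2.07 CPM in controls (log2 fold change 0.98 ± 0.64, SE), and Xist, the RNA of X inactivation, at 34.0 ± 27.0 against 25.8 ± 27.9 CPM (0.39 ± 0.68). Atrx was at 195 ± 29.5 against 253 ± 75.0 CPM, Zfp57 at 212 ± 103 against 232 ± 56.2 CPM, the methyltransferase gene Kmt2d at 613 ± 136 against 595 ± 151 CPM and Kmt2c at 451 ± 119 against 468 ± 116 CPM. Score differences were 0.04 for heterochromatin and DNA methylation genes (33 members, exact permutation p = 0.527) and 0.07 for modifiers of active chromatin (40 members, exact permutation p = 0.424). Imprinted genes differed by 0.12 (24 members, exact permutation p = 0.477). The imprinted gene Impact stood at 132 ± 86.9 against 63.4 ± 37.3 CPM (log2 fold change 1.06 ± 0.40, edgeR adjusted p 0.83) and above the control median in 8 of 8 HU embryos. Gnas stood at 84.0 ± 36.9 against 97.8 ± 28.2 CPM. Histone genes differed by 0.02 (below 0 by library size; 13 members, exact permutation p = 0.870), with H3f3b at 1393 ± 456 against 1596 ± 493 CPM and H2afz at 324 ± 195 against 276 ± 108 CPM.

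Ribosomal protein genes had 70 of 77 members with a fitted fold change above 0 and a score difference of 0.25 (exact permutation p = 0.327). Among them were Rpl41 at 524 ± 347 CPM in HU against 296 ± 215 CPM and Rps27l at 388 ± 155 against 435 ± 109 CPM. Nuclear genes of oxidative phosphorylation had 54 of 73 members above 0 and a difference of 0.18 (exact permutation p = 0.112). Among them were Cox8a at 721 ± 216 against 763 ± 124 CPM and Atp5b at 608 ± 147 against 557 ± 139 CPM. Mitochondrially encoded genes differed by -0.13 (exact permutation p = 0.581), with mt-Rnr2 at 14608 ± 2966 against 14296 ± 5454 CPM and mt-Cytb at 6672 ± 2358 against 8135 ± 3830 CPM. Heat shock and unfolded protein genes differed by 0.09 (exact permutation p = 0.555), with Hspa5 at 757 ± 430 against 511 ± 221 CPM and Atf4 at 437 ± 279 against 305 ± 137 CPM. Proteasome genes differed by 0.15 (exact permutation p = 0.335; Psmd3 at 270 ± 70.3 against 255 ± 38.6 CPM, Psmd11 at 232 ± 116 against 192 ± 50.7 CPM). Apoptosis genes differed by 0.04 (exact permutation p = 0.742; Bcl2l1 at 228 ± 60.3 against 286 ± 72.6 CPM, Birc3 at 125 ± 45.2 against 176 ± 35.8 CPM). Glycolysis genes differed by 0.01 (below 0 by library size; exact permutation p = 0.960; Ldhb at 318 ± 194 against 319 ± 112 CPM, Pkm at 290 ± 133 against 289 ± 101 CPM). Cholesterol synthesis genes differed by -0.04 (above 0 with ERCC scaling; exact permutation p = 0.739; Insig1 at 200 ± 55.3 against 220 ± 20.7 CPM, Fdft1 at 139 ± 47.9 against 176 ± 18 CPM). Core splicing genes differed by 0.04 (exact permutation p = 0.794; Snrpg at 181 ± 73.6 against 201 ± 32.1 CPM, Sf3b1 at 129 ± 37.2 against 134 ± 32.1 CPM). Interferon response genes differed by -0.02 (above 0 with ERCC scaling and in FPKM; exact permutation p = 0.883; Stat2 at 77.5 ± 16.7 against 74.7 ± 33.3 CPM, Ddx58 at 68.9 ± 26.6 against 72.7 ± 24.3 CPM). Cumulus and granulosa markers differed by -0.01 (above 0 with ERCC scaling; exact permutation p = 0.925; Hmgcs1 at 124 ± 30.2 against 131 ± 30.6 CPM, Akap12 at 99.8 ± 25.1 against 94.8 ± 21.5 CPM).

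Across the 25 lists, 19 had a higher and 6 a lower mean score in HU; 4 of the 6 turned above 0 with ERCC scaling. After adjustment 0 lists passed the exact permutation test, and adjusted over the list alone 0 members of any list passed the edgeR test. With camera at a preset correlation, 5 lists were called: maternal oocyte genes lower (adjusted p = 5.1e-06), and ribosomal protein (3.39e-05), mitosis, oxidative phosphorylation and 2-cell genes higher (0.00399 each). All 5 calls were lost with an estimated correlation (adjusted p = 0.953 for each), and fry called 0. The mixed test of fry asks whether members change in either direction and gave an adjusted p of 0.0225 for apoptosis genes. Lists of theca and stroma, immune, endothelial and erythroid markers had fewer than 5 members past the filter. Their summed levels were 16.2, 40.3, 54.6 and 1.17 CPM in HU and 20.6, 38.5, 60.7 and 1.35 CPM in control embryos.

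Library measures were compared as the technical background of these genes. Gene counts averaged 3095490 ± 464822 in HU (SD, n = 8) and 2636660 ± 503193 in controls (SD, n = 9; exact permutation p = 0.0714, adjusted p = 0.436). Detected genes averaged 14621 ± 873 against 14483 ± 379 (exact permutation p = 0.683), and 14248 ± 837 against 14221 ± 340 after thinning to 1801261 counts (exact permutation p = 0.936). Mitochondrially encoded genes took 3.43% ± 0.703 against 3.87% ± 1.27 of gene counts (exact permutation p = 0.433), and the 50 most abundant genes 35.6% ± 4.25 against 35.1% ± 5.24 (exact permutation p = 0.817). Rn45s, the 45S pre-rRNA, took 23.5% ± 4.6 against 20.9% ± 5.22 (exact permutation p = 0.282). Gene counts without Rn45s per ERCC count, a measure of RNA per library if the spike-in amount was equal, were 13.5 ± 3.26 against 12.4 ± 2.08 (exact permutation p = 0.406). None of the 10 measures passed after adjustment.

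HU embryos lay on average 89.6 from their group mean in log2 expression and control embryos 80.4, a difference of 9.28 that did not pass (exact permutation p = 0.104). With 1 minus Spearman correlation as the distance, the values were 0.192 and 0.154 (difference 0.0378, exact permutation p = 0.0209). Without control 1 the Euclidean difference was 11.3 (exact permutation p = 0.0429), and without control 3 it was 12.7 (p = 0.0354, exact permutation), so the call depends on the measure and on these embryos. The SDs of list scores, compared after seeing the data, were larger in HU for 20 of 25 lists and smaller for 5, the lowest ratio being 0.54 for glycolysis genes, and 0 ratios passed (smallest adjusted p = 0.389). They were 2.29 times as large in HU as in controls for checkpoint genes (exact permutation p = 0.0843, adjusted p = 0.389), and 17.8 times without control 1. Ratios were 2.16 for maternal genes (exact permutation p = 0.181, adjusted p = 0.451; 1.42 without HU 5) and 2.13 for proteasome genes (exact permutation p = 0.0182, adjusted p = 0.389).

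A donor score asked whether HU embryos lay nearer to the cumulus cell profile, over genes that differed strongly between the cells and the embryos. Donor-high genes were at least 8-fold higher in the cells than in the mean of all embryos, and embryo-high genes the reverse. Genes held near the donor level in most embryos were thus left out by rule, and the score cannot measure them. The 239 donor-high genes averaged 2.51 ± 0.27 in log2(CPM + 1) in HU (SD, n = 8) and 2.53 ± 0.20 in controls (SD, n = 9; exact permutation p = 0.875), and the 1309 embryo-high genes 7.05 ± 0.11 against 7.11 ± 0.05 (exact permutation p = 0.158). The score, donor-high minus embryo-high, was -4.54 ± 0.36 in HU and -4.58 ± 0.24 in controls, a difference of 0.04 (exact permutation p = 0.769), which changed sign when single embryos were left out (-0.02 to 0.13).

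Cumulus cells were set against control embryos to describe how far the embryos' transcripts stand from those of the donor cell type. Embryo RNA includes maternal transcripts laid down in the egg, so the distance is not that of the donor nucleus alone. The maternal list summed to 52615 CPM in control embryos and 402 CPM in the cells. CPM here are of library sizes without TMM factors, log2 ratios carry an added 1 CPM on both sides, and folds carry none. The median log2 ratio of all genes was -0.57, or -0.24 with Rn45s left out of the library size. The steroid synthesis genes Cyp11a1, cholesterol side-chain cleavage enzyme, and Hsd3b1 stood at 1808 CPM (95% counting interval 1791 to 1825) and 1635 CPM (1619 to 1652) in the summed cells, and at 1.12 ± 1.6 and 0.893 ± 1.22 CPM in control embryos (SD, n = 9). The counting interval does not cover the spread between cells. Single cells ran from 0 to 3977 CPM for Cyp11a1 (median 1986) and from 0 to 8133 CPM for Hsd3b1 (median 615). Spp1, osteopontin, reached 11075 CPM against 20.8 ± 16.3 CPM, a log2 ratio of 8.99. By that log2 ratio, the other leading genes on the cumulus side were Sfrp4 (log2 ratio 8.61), Efemp1 (8.56), Timp1 (8.27), Mgst1 (8.13), Nrn1 (7.59), Serpinb6b (7.21). Epdr1 was at 112 CPM in cumulus cells and 0 counts in control embryos, at least 884-fold higher in the cells. On the embryo side, Tcl1 had 0 counts in the 12 cells (at least 61069-fold lower). Also at 0 counts in the cells were C86187 (at least 44616-fold), Omt2a (at least 33690-fold), Khdc1b (at least 32441-fold), Tcl1b1 (at least 29244-fold), Oog3 (at least 21000-fold), Btg4 (at least 17778-fold) and Spry4 (at least 12685-fold). Omt2b had 4 counts and Wee2 1 count in the cells, against 4184 ± 635 and 1819 ± 171 CPM in control embryos. For Wee2 the ratio was 43766 with a counting interval of 7855 to 1728650. Several of these are multigene families, whose counts can be shared between copies.

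Maternal oocyte genes had a median log2 ratio of -6.10 (cumulus over control, 62 members, percentile 0 of random lists; -9.01 without the added 1 CPM and with genes at 0 counts at their bound), with Spin1 at 75.6 CPM in cumulus cells and 7498 ± 1696 in controls. Mitosis genes had -5.94 (percentile 0), with the cyclin gene Ccna2 at 0 counts (at least 4781-fold lower) and Ccnb1 at 4 counts. Replication genes had -3.99 (percentile 0; Pold3 at 8.23 against 402 CPM, Orc6 at 16.7 against 372 CPM). Pluripotency factors had -3.60 (percentile 0), with Obox5 and Klf17 at 0 counts in the cells. The medians were -3.27 for 2-cell genes (percentile 0; Sp110 at 0.499 against 307 CPM, Nelfa at 22 against 133 CPM) and -2.93 for break repair genes (percentile 0.06; Brca2 at 3.70 against 357 CPM). Checkpoint genes had -2.65 (percentile 0; Dbf4 at 4.99 against 1136 CPM). Heterochromatin genes had -2.21 (percentile 0.32), with Atrx at 62.6 against 250 CPM. Zfp57 had 2 counts in the cells against 232 CPM, a ratio of 2789 with a counting interval of 772 to 23033. Cumulus and granulosa markers had a median of 2.00 (49 members, percentile 100). Ribosomal protein genes had 1.82 (percentile 100; Rpl4 at 1097 against 241 CPM, Rpl10 at 681 against 119 CPM). Oxidative phosphorylation genes had 0.80 (percentile 100; Atp5b at 797 against 558 CPM, Cox8a at 171 against 764 CPM), and glycolysis genes 0.61 (percentile 99.7; Gapdh at 959 against 142 CPM, Aldoa at 732 against 161 CPM). Against HU embryos in place of controls the medians were -5.96 for maternal genes, -3.87 for 2-cell genes and 1.90 for cumulus markers.

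Other lists lay nearer to the random lists, whose medians were themselves below 0. Proteasome genes stood at 0.21 (percentile 99.7; Psmd3 at 67.0 against 256 CPM, Psmd5 at 35.9 against 202 CPM) and cholesterol synthesis at 0.14 (percentile 98.5; Fdps at 672 against 54.5 CPM, Insig1 at 30.3 against 220 CPM). Apoptosis genes stood at -0.20 (percentile 94.2; Bcl2l1 at 17.4 against 285 CPM, Birc3 at 11.6 against 177 CPM), and above 0 without Rn45s. Core splicing stood at -0.36 (percentile 94.0; Snrpg at 150 against 199 CPM, Snrpb at 141 against 90.9 CPM), and heat shock genes at -0.45 (percentile 85.9; Hsp90ab1 at 1148 against 291 CPM, Hspa5 at 384 against 514 CPM), both above 0 without Rn45s. Housekeeping genes of genome activation stood at -0.57 (percentile 82.5; Npm1 at 569 against 515 CPM, Eif1 at 289 against 869 CPM) and nucleotide synthesis at -0.81 (percentile 64.1; Mthfd2 at 50.5 against 400 CPM, Dut at 17.9 against 398 CPM), both above 0 without Rn45s. Imprinted genes stood at -0.83 (percentile 47.4; H13 at 227 against 60.9 CPM, Gnas at 197 against 100 CPM) and active chromatin modifiers at -0.97 (percentile 51.1; Kmt2d at 59.4 against 589 CPM, Kmt2c at 29.4 against 465 CPM). The p53 targets stood at -1.46 (percentile 15.7; Rrm2b at 4.49 against 303 CPM, Fdxr at 193 against 21.2 CPM) and histone genes at -0.45 (percentile 18.1; H3f3b at 390 against 1581 CPM, H2afz at 387 against 274 CPM). Over single cells, H2afz had a median of 178 CPM, below the control embryos, and a highest value of 3789 CPM. Mitochondrially encoded genes stood at -0.51 (percentile 1.75; mt-Rnr2 at 20230 against 13980 CPM, mt-Cytb at 1615 against 8061 CPM). The interferon list stood at -0.28 (percentile 68.0; Bst2 at 143 against 23.0 CPM, Stat2 at 3.70 against 74.5 CPM) and theca and stroma markers at -0.35 (percentile 70; Ptch1 at 25.9 against 3.88 CPM, Pdgfrb at 2.45 against 8.12 CPM). Immune markers stood at 0.07 (percentile 97.8; Lyz2 at 6.48 against 6.03 CPM, H2-Aa at 0.416 against 16.6 CPM), and at -0.65 without cells 2 and 11. Without the added 1 CPM, and with genes at 0 counts at their bound, some of these medians were lower. They were -0.48 for immune, -1.73 for theca and stroma, -1.24 for interferon, -1.78 for histone and -1.59 for mitochondrially encoded genes. Proteasome and cholesterol genes stayed near their values, at 0.21 and 0.16. Of 14 immune markers, 0 were 4-fold higher in the cells and 2 were 4-fold lower. Endothelial markers stood at -2.27 (percentile 2.39; Pecam1 at 1.70 against 37.1 CPM, Flt1 at 0.333 against 12.1 CPM), and at -4.45 without the added 1 CPM. Of erythroid markers, Alas2 was at 0.998 against 1.32 CPM.

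**Figure D3:**
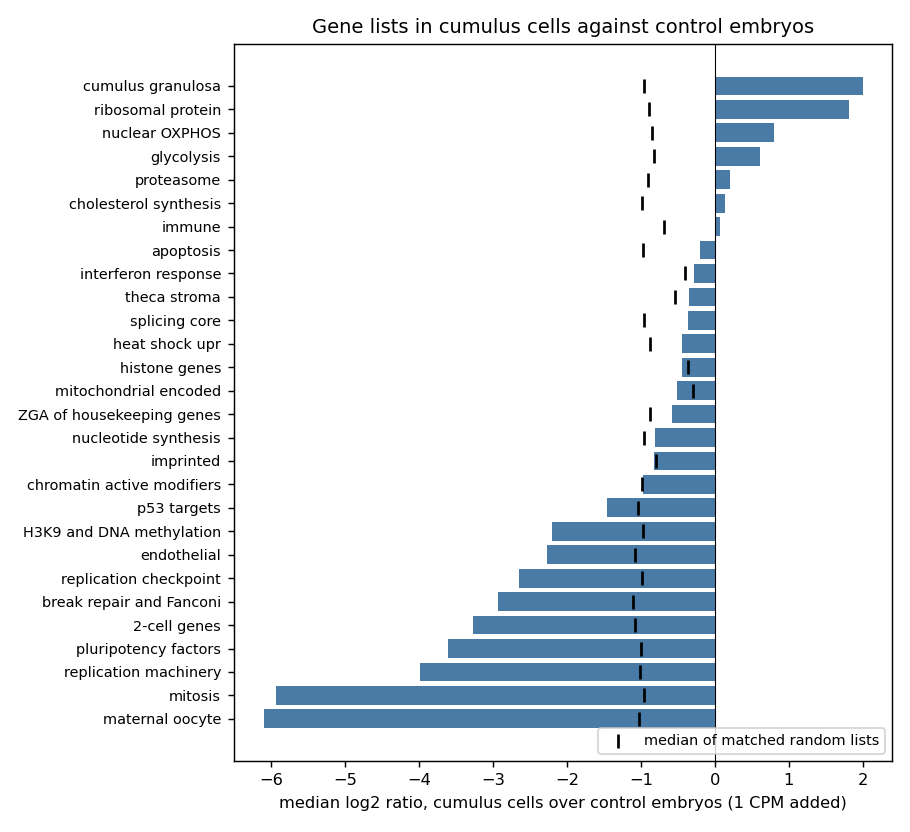
Median log2 ratio of the summed cumulus cells over the mean of 9 control embryos for each gene list (bars), with the median of matched random lists as a black mark. Maternal oocyte genes at -6.10 and cumulus and granulosa markers at 2.00 are the ends of the range. Housekeeping, nucleotide synthesis, heat shock, apoptosis and splicing genes lie above 0 when Rn45s is left out of the library size.

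Across genes, which are not independent replicates, the log2 fold changes of HU and of cumulus cells against the same controls had a Pearson correlation of 0.212 and a Spearman correlation of 0.234. For comparison, the group labels of all embryos were shuffled, so both drawn groups, the reference included, could hold HU and control embryos. These shuffled groups gave a mean Pearson correlation of 0.0877 (-0.0603 to 0.236, the middle 95% of 1000 draws). Controls split between the comparisons gave 0.116 (0.0286 to 0.179 over 252 splits), below the observed value. The covariance was 0.202 against 0.0815 in shuffled groups (-0.0522 to 0.236). The Spearman correlation of shuffled groups was 0.0853 (-0.0666 to 0.248). Each of the 3 observed values lay within the range of the shuffled groups.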

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

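The ERCC share, the tests against other splits of the embryos and the use of the planned list test to weigh the 2-cell spread were chosen only after their results were seen. Among 208 groups of embryo values checked, 11 had 1 embryo far from the rest by Dixon's test, and chance gives about 1 in 20, or 10.4 here.

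In the 2-cell list, control 3 scored 6.79, apart from the other 8 controls at 3.80 to 4.78. The 17 scores spanned 3.21 on the log2 scale. After thinning to equal counts the range was 101% of that value, which argues against sequencing depth. With ERCC scaling it was 3.50, or 109%. The percentage alone cannot decide, because TMM scaling already removes much of a rise shared by most genes. Scaling by spike-ins does not depend on the shares of other genes. If the spike-in amount was equal, the range of 3.50 argues against a loss of maternal RNA that would raise every other share. Whether HU raises the score stays open (exact permutation p = 0.312). Control 3 had the fewest detected genes of the controls (13875, but more than control 9, at 13625, after thinning), and HU 4, HU 7 and HU 5, with scores of 6.66, 6.10 and 5.88, the fewest of the HU embryos (12887, 13892 and 14293), while HU 3, at 5.85, had 15192, so a link of the score to library complexity stays open.

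The checkpoint list score of control 1 was 5.62 against 5.82 to 5.85 in the other controls. Among controls, control 1 also had the highest mitochondrial share, 6.61% against 2.21% to 4.34%, and the highest ERCC share, 8.45% against 4.94% to 6.46%. The p53 target score of HU 1 was 4.73 against 5.15 to 5.38 in the other HU embryos. Ldhb in HU 1 stood at 9.60 in log2(CPM + 1), against 7.21 to 8.33. In HU 4, Kdm4d was at 0 against 2.05 to 3.88 and Rrm2 at 8.65 against 7.14 to 7.79. Sf3b1 in HU 7 stood at 7.76 against 6.55 to 7.04, Psmd3 in control 2 at 8.47 against 7.85 to 8.04, and Ei24 in control 7 at 6.34 against 7.07 to 7.66.

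Other splits of the 17 embryos were compared with the real one. Every split reaches a count of 0 calls (100 of 100, the real one included, with the highest other at 649), so the splits say nothing about that count. For the 671 genes at an unadjusted p under 0.05, 21 of 100 splits gave as many or more, the real one included (20 of the 99 others, the highest at 2519), and chance cannot be excluded. The splits with 649, 151 and 70 calls were also those with the 3 largest differences in mean 2-cell score (-1.44, -1.41 and -1.21, against 0.51 in the real split), which points to a structure of the embryos; whether it is independent of the treatment was not tested.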

How the results depend on the processing

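Scaling by ERCC counts, library sizes without Rn45s, the 2-cell score covariate and the omission of the embryo with the fewest genes per group were chosen after seeing the data. Of 34 alternative fits of HU against control, 31 called 0 genes. DESeq2 called 2 higher and 1 lower, the detected-gene covariate 1 higher (Etnk1, adjusted p 0.0429), and the fits without single embryos 0 to 1 higher (Etnk1 without HU 8, adjusted p 0.0160). Etnk1 had a log2 fold change above 0 in each. With embryo numbers as a replicate block, 0 genes and 0 lists were called and the genes at an unadjusted p under 0.05 numbered 274 higher and 262 lower. Same-numbered embryos correlated at -0.102 to 0.188, only 1 of 8 pairs above 0.1, and 0 embryos matched their own number best. These values give no sign that the numbers pair embryos, but 8 pairs cannot exclude a shared day or female. The depth filter removed 0 embryos and gave no fit. Over 66 named genes, 2243 gene-by-setting values included 2159 with the direction and side of the threshold kept, 4 that passed, and 80 that changed sign, with absolute values of at most 0.24 and none past the threshold. The cause was not tested.

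Pkm (0.00 as reported) turned to -0.00742 with 10 counts in 8 embryos, -0.00178 with DESeq2, -0.00170 with its size factors, -0.0580, -0.0587 and -0.0580 in FPKM fits, -0.0162 with 3 groups, -0.0177 by library size, -0.0122 without abundant genes, -0.0192 with voom, -0.0242 unfiltered, -0.0589 under the block. H2afz turned to -0.00936, -0.0105 and -0.00936 in FPKM fits. With ERCC scaling, Sf3b1 turned to 0.12, Hmgcs1 0.0815, Cox8a 0.0290, Ddx58 0.11, Kmt2c 0.14, Brca2 0.0588, Ldhb 0.18, Orc6 0.0567, Chek1 0.14, and the scores of cumulus markers 0.10, pluripotency 0.11, interferon 0.10 and cholesterol 0.0889. With the 2-cell score as covariate, Stat2 turned to -0.0120, Psmd11 -0.0517, Ccnb1 -0.0568, AF067063 -0.12, H2afz -0.13, Zfp352 -0.24, Kmt2c 0.0722, Ldhb 0.11, Chek1 0.00197, Ei24 -0.16 and Pkm -0.21. AF067063 and Zfp352, at 0.87 and 1.07 before adjustment, are members of the 2-cell list. Adjusting them for a score of that list removes their difference largely by construction. Without the embryo with the fewest genes per group, Sf3b1 turned to 0.0153, Ccnb1 -0.0395, Kmt2c 0.0973, Ei24 -0.0765 and Pkm -0.0937; without Rn45s, Ldhb to 0.000474. List scores turned for glycolysis (-0.0200) and histones (-0.00508) by library size, interferon (0.0434) and histones (-0.000785) at a pseudocount of 10 CPM, and in FPKM for nucleotide synthesis (-0.00320), interferon (0.00659), glycolysis (-0.00993) and histones (-0.0118). Donor-high genes turned to 0.0606 at 4-fold and 0.000144 in FPKM. Camera called 5 lists at a preset correlation and 0 with an estimated correlation (adjusted p = 0.953 for each of the 5). The spread passed with Spearman distance (difference 0.0378, exact permutation p = 0.0209), without control 1 (exact permutation p = 0.0429) and without control 3 (exact permutation p = 0.0354).

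Over single embryos left out, values ran from -0.0523 to 0.13 for Stat2, -0.19 to 0.0876 for Pkm, -0.22 to 0.0205 for Sf3b1, -0.0469 to 0.13 for mt-Rnr2, -0.0251 to 0.12 for Kmt2d, -0.35 to 0.10 for Ldhb, -0.22 to 0.0251 for Ddx58, -0.14 to 0.0307 for Kmt2c, -0.0186 to 0.16 for Psmd3, -0.21 to 0.00418 for Orc6, -0.0280 to 0.24 for Ei24, -0.00730 to 0.15 for Akap12 and -0.0297 to 0.31 for Klf17. For list scores they ran from -0.0558 to 0.0664 (glycolysis), -0.0213 to 0.0870 (apoptosis), -0.0712 to 0.0530 (cumulus markers), -0.0322 to 0.0966 (histones), -0.11 to 0.0413 (interferon), -0.0620 to 0.0244 (pluripotency), -0.0957 to 0.00935 (cholesterol) and -0.0180 to 0.10 (splicing). Among lists that kept their sign, differences ran from 0.00726 to 0.20 (housekeeping), 0.00335 to 0.0758 (checkpoint) and 0.0324 to 0.16 (replication). Break repair ran from 0.0517 to 0.13, p53 targets from 0.0426 to 0.14 and mitosis from 0.11 to 0.30. Ribosomal protein genes ran from 0.13 to 0.36, heat shock from 0.0232 to 0.16, proteasome from 0.0749 to 0.22 and imprinted from 0.0410 to 0.19. Values ran from -0.0235 to 0.13 for the donor score, from -0.0732 to 0.0405 for donor-high genes, and for the spread from 6.21 to 12.7. In cumulus cells over controls, the maternal median was -5.40 and that of cumulus markers 1.51 in FPKM, and the latter 2.94 without Rn45s. Cumulus cell 10 had 317195 gene counts, the fewest of the 12 cells.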

Other observations

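Within the 8 HU embryos, the 2-cell list score was correlated with other scores, a relation chosen for testing only after the scores were seen. It was positively related to the score of housekeeping genes of genome activation (Pearson r = 0.943, exact permutation p = 0.00243, adjusted p = 0.0292; Spearman rho = 0.952, adjusted p = 0.0134) and with ribosomal protein genes (r = 0.917, exact permutation p = 0.00389, adjusted p = 0.0312; rho = 0.929, adjusted p = 0.0134). Imprinted genes were negatively related (r = -0.956, exact permutation p = 0.000868, adjusted p = 0.0208; rho = -0.952, adjusted p = 0.0134). Without the 2 embryos farthest from the median score, r was 0.910, 0.938 and -0.954 over 6 embryos. Mitosis (rho = 0.929, exact permutation p = 0.00223, adjusted p = 0.0134), proteasome and splicing genes passed by rank alone. The 24 relations were adjusted together, and the maternal list showed r = -0.244 (exact permutation p = 0.570) and rho = 0.02.

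In the 9 control embryos r was 0.842 for housekeeping genes (exact permutation p = 0.00828, adjusted p = 0.199) and 0.794 for ribosomal protein genes (exact permutation p = 0.0216, adjusted p = 0.242). Spearman rho was 0.600 (exact permutation p = 0.0968, adjusted p = 0.332) and 0.783 (exact permutation p = 0.0172, adjusted p = 0.138). Without the 2 farthest embryos r was 0.121 and 0.160, so the Pearson values rest on those embryos. Imprinted genes gave r = -0.504 (exact permutation p = 0.160). The difference between the groups in these relations was not tested. Detected genes were also set against the 2-cell score, chosen after the scores were seen. After thinning, r was -0.745 in HU embryos (exact permutation p = 0.0302, adjusted p = 0.0604 over 4 relations; rho = -0.690, exact permutation p = 0.0694, adjusted p = 0.139), and -0.781 without the 2 farthest. In controls it was -0.262 (exact permutation p = 0.469, adjusted p = 0.469; rho = 0.0167, exact permutation p = 0.982). The relations between list scores were not separated from that with detected genes. Zfp352, of the 2-cell list, had 18 to 290 counts per control embryo and 33 to 826 per HU embryo, with 826 in HU 4 and 539 in HU 3.

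Cumulus cells 2 and 11 were looked at because they held counts of leukocyte genes; the tests were specified before their results were seen. Cell 2 had 281 counts in 9 genes of the immune list, among them 151 of Lyz2 and 40 of Cd68, and cell 11 had 57, among them 49 of Ptprc, the CD45 gene, while the other cells had 0 to 45. Of the 16 list genes, 13 also had counts in embryos. An immune cell in place of cell 11 is argued against by its cumulus and granulosa markers, which lay at a median log2 ratio of 0.00386 to the other cells. In cell 2 that ratio was -1.44 with 490 counts of Cyp11a1, between the bounds set, so an immune cell or a mixture could not be excluded. Cell 10, of like yield (0.173 against 0.172 gene counts without Rn45s per ERCC count), had a lower ratio of -2.15 with 0 immune counts, so a low ratio alone does not show an immune cell. Low RNA yield as the source was checked in cells 7 and 10, of lower or like yield. They had 0 immune counts where the share of cell 11 would give 124 and 17.9. Reads without molecular identifiers are not independent, however. For Cd68, cells 4, 2 and 9 had 29, 40 and 45 counts and most others 0. The 0 counts in cells 7 and 10 therefore cannot decide whether low yield was the source.

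Cell 10 had 0 counts in mitochondrially encoded genes and 73.5% of its counts in ERCC spike-ins, and cell 2 had 86.6% of its gene counts in Rn45s.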
